A study of Mus musculus with 12 samples.

How the data were processed

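The study measured RNA of mouse peripheral blood in 12 libraries, 4 each at day 0, day 2 and day 7 of an infection with Salmonella enterica serovar Typhimurium LT2. Libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. Reads were processed with Bowtie and R 3.4.2, per the submitters' processing notes. The version and settings of Bowtie, the genome build, the annotation and the way reads were counted are not given in the sources used here.

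The deposited table holds log2 values for 13611 transcripts and 12 libraries, and no column was left unused. That these are log2 of a count plus 1 was tested on the table, since raising 2 to each value and subtracting 1 gave whole numbers for all 163332 values within 1e-08 of the count plus 1, with a largest deviation of 3.47e-09. The counts used here are these recovered values, and they sum to 5218045 to 18054639 per library. Transcript identifiers were matched to gene symbols by accession in a RefSeq table of assembly GRCm38.p6 (12832 transcripts) and in GENCODE M21 (31 transcripts). The 748 transcripts without a symbol held 0.0500% to 2.26% of the counts of a library and were kept under their identifiers. Transcripts sharing a symbol were summed, which applied to 386 of 12438 symbols and left 13186 genes. The references may differ from the build the authors used, and they served for names only, so no coordinates are given.

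Counts were scaled to CPM with trimmed-mean-of-M-values (TMM) factors, computed with an own implementation in R, and genes with at least 1 CPM in at least 4 libraries were kept, which left 6889. Log2 of CPM plus 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), with all 12 libraries and the 3 days in one fit. Tests were two-sided and p-values were adjusted with Benjamini-Hochberg over the 6889 genes, with a threshold of 0.05. The test for counts that had been set as first choice was not used, and the one set for normalized values was used in its place. This choice went by the deposited unit, which is log2. The recovered whole counts would have allowed the test for counts. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The comparisons, the gene lists, the named-gene rule and the alternatives other than those named as added were fixed before the data were examined.

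Gene lists were tested with camera in limma, with the preset correlation of 0.01 and, as an alternative, an estimated one. Of 39 lists, the 33 with at least 5 genes tested were used, and p-values were adjusted over these lists within each comparison. Named genes were chosen by 3 rules. The first names 30 key genes whatever their result. The second names, in each comparison, the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM, no overlap between the 4 values of each day and a symbol that is not a gene model name. The third names, for each list that passed, up to 4 members with the smallest p in the direction of the list and 1 member that passed in the other direction. Some of the genes these rules name are not reported here, and they stay in the counts.

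The labels give replicate numbers 1 to 4 on each day but do not say that equal numbers share an animal. This was checked in the data, after removing the mean of each day. Same-numbered libraries of different days correlated across genes with r from 0.31 to 0.82 (12 pairs), and differently numbered ones with r from -0.59 to 0.22 (36 pairs). Without 302 genes high in the libraries numbered 4, the lowest same-number r was 0.14 and the highest other-number r 0.07. Day accounted for 45.4% of the variance, number for 36.0% and the rest for 18.5%. The replicate number was therefore also fitted as a block, and that value is printed where it changes a call or moves a printed count by more than 1.5 times. Results without the block are the main ones because the design fixed that choice.

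The test was checked on simulated data for the comparison of day 2 with day 0, with 50 genes changed at each fold. Without the block, limma recovered 4% of 2-fold, 24% of 4-fold, 68% of 8-fold and 100% of 16-fold changes among 5234 genes, and 2 of 100 calls were false. With the block it recovered 2%, 70%, 94% and 100% among 5616 genes, and 4 of 137 calls were false. Changes near 2-fold are thus mostly missed with 4 libraries per day.

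The alternatives tried were median-of-ratios size factors, quantile normalization, no filter on low values, a pseudocount of 0.1, the globin genes left out, the replicate block, only the groups compared, a test against a fold of 1.5, the estimated correlation for lists, the day 0 libraries split between comparisons, and each library left out in turn. Alternatives added after the data were seen were voom weights, library totals without TMM factors, transcripts not summed, and the libraries numbered 4 left out, with and without the block. For the gene lists, the runs without a filter and with a pseudocount of 0.1 were also added. DESeq2 was not used, and the comparisons set out for it were not run, by the same choice to go by the deposited log2 unit.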

Results

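Peripheral blood RNA of mice was sequenced at day 0, day 2 and day 7 of an infection with Salmonella enterica serovar Typhimurium LT2, an intracellular gut bacterium, with 4 libraries per day. The series describes day 0 as the time before infection. The deposited table held 5218045 to 18054639 counts per library, with a median of 10351352. At this depth 3 counts in a library equal between 0.166 and 0.575 CPM, a limit that covers counting error only. Blood libraries were dominated by few transcripts, with the 10 most abundant genes of a library holding 43.5% to 62.7% of its counts. The labels do not say whether the 4 libraries of a day come from separate animals, so the p-values measure the spread between these samples.

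Of 6889 genes tested with limma, 1817 changed over the 3 days at a Benjamini-Hochberg adjusted p under 0.05, and 3030 did so with the replicate number as a block. The transcripts most abundant on average differed between day 0 and day 2. At day 0, Alas2 and Hba-a1 held on average 15.9% and 14.8% of the counts. At day 2, Isg20 and Sod2 held on average 15.3% and 12.9%, and at day 7 they held 12.8% and 8.47%. Libraries of a day were unlike, with Hba-a1 at 1.12% to 24.2% at day 0. Isg20 held 2.32% to 28.0% at day 2 and 1.21% to 23.7% at day 7. The top gene of the day 2 libraries numbered 1 to 4 was Sod2, Isg20, Isg20 and Cd24a. At day 7 it was Cd6, Isg20, Mmp8 and S100a8. The 5 globin genes in the table together fell from 14.9% ± 9.78 (SD, n = 4) of the counts at day 0 to 0.316% ± 0.191 at day 2 and 0.468% ± 0.512 at day 7. At day 0 this share was almost all Hba-a1, at 14.83% of 14.85% on average. The fall therefore describes a single gene and not the globin family.

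**Figure D1:**
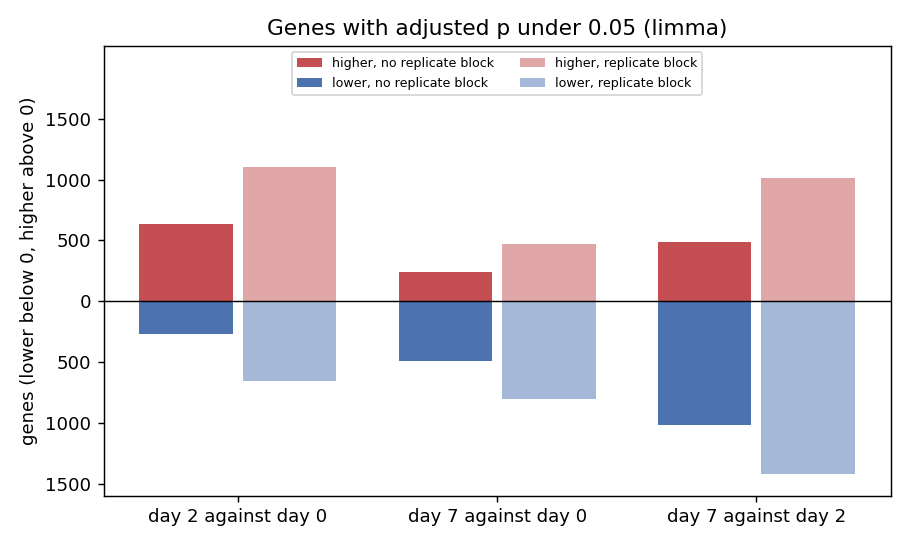
Genes with a limma adjusted p under 0.05 in each comparison, drawn above 0 when higher and below 0 when lower at the later day, with and without the replicate number as a block. The counts without the block were 911, 740 and 1511 genes.

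The comparison of day 2 with day 0 asks how blood transcripts differ early in the infection. Among the genes that were higher at day 2 were 7 of 12 interferon-gamma-inducible, 7 of 13 oxidative killing and 7 of 20 glycolysis genes. Among the lower genes were 16 of 31 erythroid, 6 of 41 ribosomal protein and 3 of 14 B cell genes, and 0 lists passed as sets with an estimated correlation between genes. In all, 637 genes were higher and 274 lower out of 6889, and with the replicate block 1106 were higher and 654 lower. The higher genes made up 69.9% of the calls, and this share varied with the setting. It was 75.9% with median-of-ratios factors in place of TMM, 59.7% with library totals and 57.7% after quantile normalization. With only the groups compared in the filter and fit it was 53.2%, and against a fold of 1.5 it was 77.1%.

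Among genes that passed, kept the 4 values of each day apart, reached a mean of 10 CPM and were not gene models, those with the largest rise at day 2 were Retnla, Sod2, Mmp8, Slc11a1, Cd6, Acsl1, Ms4a8a and B3gnt5. The superoxide dismutase gene Sod2 went from a mean log2(CPM + 1) of 8.17 ± 0.52 (SD, n = 4) at day 0 to 16.87 ± 0.84 at day 2, a log2 fold change of 8.70 (SE 0.53, limma adjusted p 1.86e-06). Slc11a1, the phagosomal metal transporter known for resistance to Salmonella, rose by 8.37 (SE 1.07, limma adjusted p 0.000594), and Retnla by 8.81 (SE 1.21, limma adjusted p 0.000875). Mmp8, Cd6, Acsl1, Ms4a8a and B3gnt5 rose by 7.78 to 8.48 on the log2 scale. The receptor genes Cd14 and Tlr4 rose by 6.21 and 7.11, with limma adjusted p of 0.0103 and 0.00897. S100a9 rose by 7.10 (SE 2.13, limma adjusted p 0.0437). S100a8 rose by 3.71 (SE 1.64) without passing, at a limma adjusted p of 0.155, and passed with the replicate block at 0.0232.

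Of the 12 interferon-gamma-inducible GTPase and chemokine genes tested at day 2, 7 were higher, 0 lower and 5 did not pass, and 8 were higher when adjusted over the list alone. Irf1, Igtp, Gbp7 and Gbp4 had the smallest p-values and rose by 3.67, 3.88, 3.30 and 4.45. Gbp2 rose by 5.56 (SE 1.55, limma adjusted p 0.0323). Irgm1 fell by 0.56 (SE 0.31) without passing, at a limma adjusted p of 0.254. Among 13 oxidative and nitrosative killing genes 7 were higher and 2 lower, or 8 and 3 when adjusted over the list alone. The NADPH oxidase subunits Ncf1 and Ncf4 rose by 6.17 and 3.82, and Gpx1 fell by 3.36. Among 20 glycolysis and hypoxia genes 7 were higher and 1 lower, or 10 and 2 when adjusted over the list alone and 11 and 2 with the replicate block. The glucose transporter Slc2a3 rose by 5.70, Slc16a3 by 2.93, Gapdh by 2.05 and the scarce Ldha by 1.80, while Aldoa fell by 2.49. Among 14 genes of antigen presentation by MHC class I, 3 were higher and 1 lower, or 8 and 1 when adjusted over the list alone and 7 and 1 with the replicate block. Psmb9, Psmb10 and Tapbp rose by 3.62, 2.95 and 2.58, and Calr fell by 2.22.

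Within the same limits the largest falls at day 2 were in Bpgm, Fech, Ranbp10, Slc25a37, Hba-a1, Isca1, Car2 and Hagh. Of 31 erythroid and reticulocyte genes tested 16 were lower and 1 higher, or 18 and 1 when adjusted over the list alone, and their median log2 fold change was -2.19. Bpgm went from a mean log2(CPM + 1) of 11.17 ± 0.40 to 4.04 ± 1.18 (SD, n = 4), a change of -7.13 (SE 0.84, limma adjusted p 0.000387). The heme synthesis gene Fech fell by 6.92 (SE 0.70, limma adjusted p 0.000203) and Alas2 by 3.31 (SE 0.68, limma adjusted p 0.00733). Ranbp10, Slc25a37, Hba-a1, Isca1, Car2 and Hagh fell by 4.64 to 5.99, and Blvrb fell by 3.51. Hba-a1 has a near-identical copy, so its reads are uncertain. Isg20, listed among the erythroid genes, rose by 4.77 (limma adjusted p 0.00818). Of 41 cytosolic ribosomal protein genes 6 were lower and 0 higher, or 10 and 0 when adjusted over the list alone, and 24 were lower with the replicate block. Rplp1, Rplp0, Rps24 and Rpl6 fell by 4.09, 3.46, 2.10 and 1.97. Of 14 B cell genes 3 were lower and 0 higher, or 7 and 0 both when adjusted over the list alone and with the replicate block, with Cd79b and Ralgps2 falling by 2.52 and 1.34. Of 18 platelet genes 1 was lower, or 0 when adjusted over the list alone and 3 with the replicate block, and this 1 was Gp5, which fell by 2.03. Of 20 cell cycle genes 2 were lower, both also when adjusted over the list alone, and 5 with the replicate block. The 2 were Ube2c, which fell by 3.98, and Tk1, which fell by 1.05. Ifng, Il1b, Tnf, Lcn2, Hp, Cd79a, Cd8a, Ncr1, Pf4 and C1qa did not pass at day 2, with changes from -1.77 for Pf4 to 0.42 for Tnf.

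As sets, 9 of 33 lists passed at day 2 with camera in limma, with adjusted p from 7.12e-11 for the erythroid and for the ribosomal protein genes to 0.0475 for MHC class I genes, and 0 lists passed with an estimated correlation between genes, where the smallest adjusted p was 0.367 and 3 lists had an unadjusted p under 0.05. With the replicate block the MHC class I genes had a camera adjusted p of 0.0539 in limma and no longer passed. Without the libraries numbered 4 the interferon-gamma, oxidative killing, MHC class I and glycolysis sets did not pass. Gbp2 and Gp5 did not pass without 6 of the 8 libraries, each taken singly, Calr without 5, Mmp8 without 4, and Cd79b and Rpl6 without 2. S100a9 did not pass with any 1 of the 8 libraries left out, at limma adjusted p of 0.0565 to 0.124, and Tk1 did not pass without 7 of the 8, each taken singly.

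**Figure D2:**
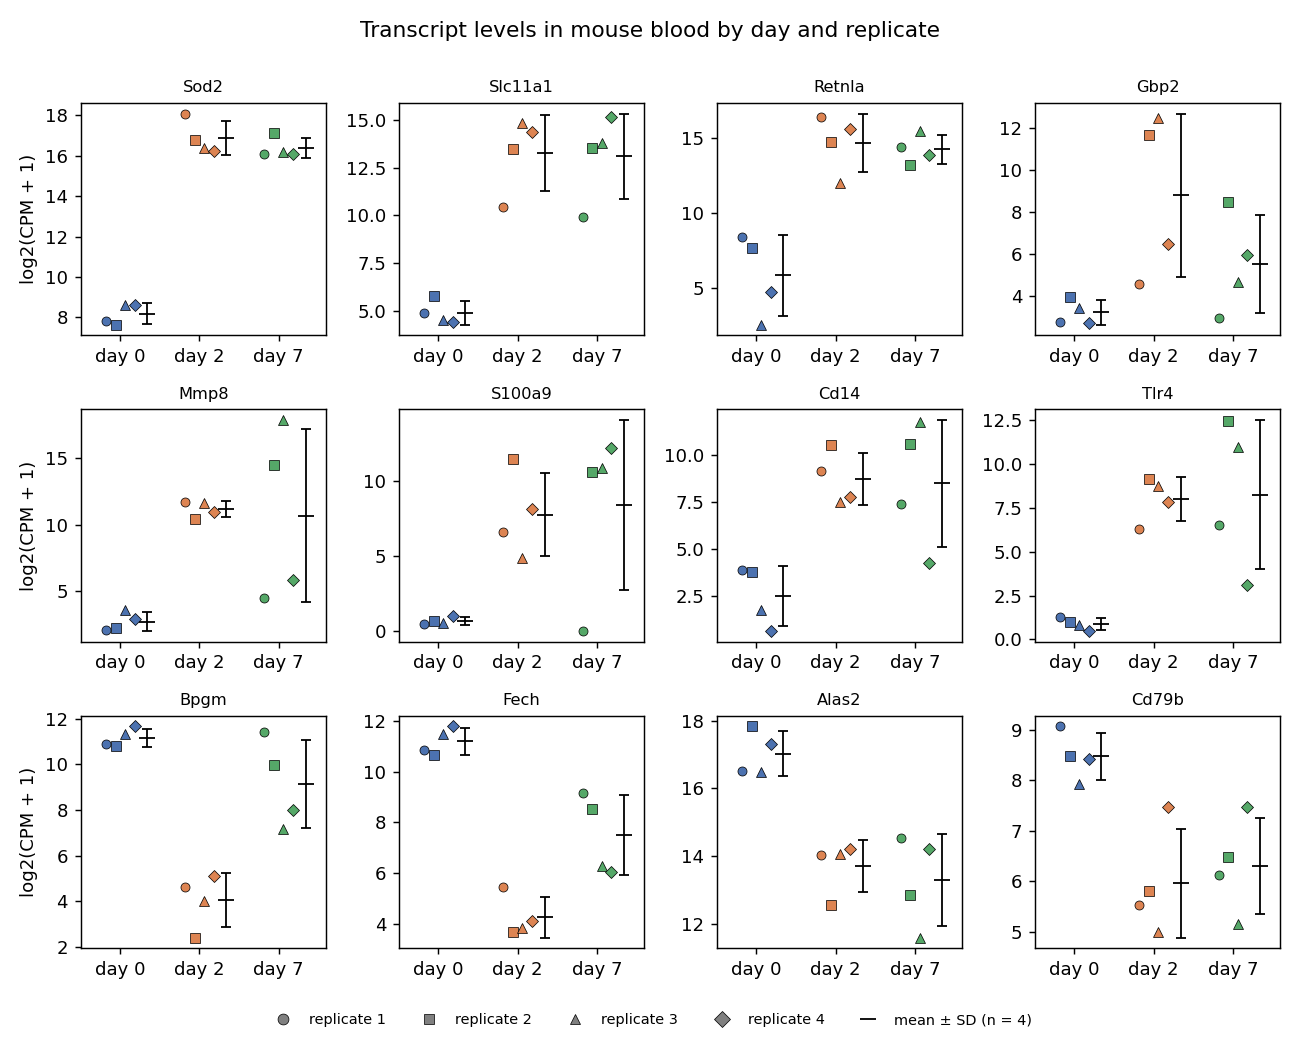
Log2(CPM + 1) of 12 named genes in each library at day 0, day 2 and day 7, with a marker shape per replicate number and bars for the mean and SD of 4 libraries. Sod2 was at 8.17, 16.87 and 16.37 on average at the 3 days.

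The comparison of day 7 with day 0 asks which differences from day 0 were present later in the infection. Among the genes that were higher at day 7 were 5 of 13 oxidative killing, 4 of 20 glycolysis, 4 of 18 mature neutrophil and 3 of 17 complement genes. Among the lower genes were 3 of 14 B cell, 6 of 20 cell cycle, 8 of 41 ribosomal protein and 5 of 37 oxidative phosphorylation genes, and 0 lists passed as sets with an estimated correlation between genes. Fewer genes rose than fell, with 244 higher and 496 lower out of 6889, and 468 higher and 807 lower with the replicate block. The higher genes made up 33.0% of the calls, 39.9% with median-of-ratios factors in place of TMM and 22.6% with library totals.

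Within the limits given for day 2, Retnla, Sod2, Slc11a1, Batf3, Mmp8, Cd6, Cd274 and Ms4a8a had the largest rises at day 7, from 7.63 to 8.36 on the log2 scale. Sod2 stood at 16.37 ± 0.50 (SD, n = 4), a rise of 8.20 over day 0 (SE 0.53, limma adjusted p 3.96e-06). Batf3 rose by 8.07 (SE 1.11, limma adjusted p 0.00109) and Slc11a1 by 8.20 (SE 1.07, limma adjusted p 0.000915). The immune checkpoint ligand Cd274 rose by 7.71 (SE 1.89, limma adjusted p 0.0175). Cd14 and Tlr4 remained higher than at day 0, by 5.97 and 7.36. S100a9 rose by 7.74 (SE 2.13, limma adjusted p 0.0325) in 3 of 4 same-numbered pairs, since 1 day 7 library had a log2(CPM + 1) of 0. S100a8 rose by 5.01 (SE 1.64, limma adjusted p 0.0690), and passed with the replicate block at 0.00557. Within these limits Luc7l3, Nusap1, Rbm3, Ppp1cb, Tmem123, Bnip3l, Oip5os1 and Smc4 had the largest falls, from -4.80 to -4.39. Smc4 fell by 4.39 (SE 0.43, limma adjusted p 0.000345) and Luc7l3 by 4.80 (SE 0.56, limma adjusted p 0.000633).

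Of 13 oxidative and nitrosative killing genes at day 7, 5 were higher and 3 lower, the same counts as when adjusted over the list alone. Ncf1 rose by 6.24 and Ncf4 by 3.62, and catalase, Cat, fell by 2.27. Of 12 interferon-gamma-inducible GTPase and chemokine genes 2 were higher and 0 lower, also when adjusted over the list alone, and Igtp rose by 3.94. Gbp2 was no longer past the threshold, at 2.28 (SE 1.55, limma adjusted p 0.428) over day 0. Among 12 anti-inflammatory and feedback genes 2 were higher, also when adjusted over the list alone. These were Arg2, which rose by 6.60, and Socs3, which rose by 2.70. Among 17 complement and coagulation genes 3 were higher and 0 lower, also when adjusted over the list alone, and these were Serping1, Thbd and C5ar1, which rose by 6.23, 4.14 and 3.32. Of 18 mature neutrophil genes 4 were higher and 1 lower, also when adjusted over the list alone. S100a11 rose by 6.30, Trem1 by 5.35 and Msrb1 by 2.48, while Cxcr4, at a mean log2(CPM + 1) of 1.90 at day 0, was listed at 0 in each day 7 library. Of 11 secondary granule genes 2 were higher, Mmp8 and S100a9, and 4 when adjusted over the list alone, or 5 with the replicate block. Of 20 glycolysis and hypoxia genes 4 were higher and 0 lower, also when adjusted over the list alone, and 6 and 1 with the replicate block, with rises of 4.72 for Slc2a3, 2.49 for Slc16a3, 1.88 for Pkm and 1.79 for Gapdh.

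Of 20 cell cycle genes 6 were lower and 0 higher at day 7, or 10 and 0 when adjusted over the list alone. Mcm6, Pcna, Stmn1 and Ccnb2 fell by 4.17, 3.31, 2.77 and 2.74. Of 41 ribosomal protein genes 8 were lower and 0 higher, or 18 and 0 when adjusted over the list alone, and 23 were lower with the replicate block. Rplp1, Rps24, Rps25 and Rpl23 fell by 4.37, 4.04, 2.84 and 2.26. Of 14 B cell genes 3 were lower and 0 higher, also when adjusted over the list alone. Blnk, Ralgps2 and Cd79b fell by 2.41, 2.36 and 2.17. The T cell gene Cd8a fell by 2.94 (SE 0.74, limma adjusted p 0.0197). Of 37 oxidative phosphorylation genes 5 were lower and 0 higher, or 6 and 0 when adjusted over the list alone, and 11 were lower with the replicate block. Cox6c, Ndufa1, Sdhb and Cox5a fell by 3.28, 2.62, 2.61 and 2.13. Alas2 stayed below day 0, by -3.73 (SE 0.68, limma adjusted p 0.00368), but the erythroid genes as a set did not pass, with 4 lower and 1 higher of 31, or 7 and 1 with the replicate block, and a camera adjusted p of 0.0741 in limma. Irgm1, Ifng, Il1b, Tnf, Lcn2, Hp, Cd79a, Ncr1, Pf4 and C1qa did not pass at day 7. Their changes ran from -1.27 for Pf4 to 2.08 for Hp, and Tnf, at 0.56, passed with the replicate block at a limma adjusted p of 0.0475.

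As sets, 11 of 33 lists passed at day 7 with camera in limma, with adjusted p from 5.03e-10 for ribosomal protein genes to 0.0493 for the secondary granule and the anti-inflammatory genes, and 0 lists passed with an estimated correlation, where the smallest adjusted p was 0.170 and 5 lists had an unadjusted p under 0.05. The anti-inflammatory genes did not pass with the replicate block, at a camera adjusted p of 0.0556 in limma, nor under any other scaling or filter tried. Without the day 7 library numbered 2 the interferon-gamma, mature neutrophil, secondary granule, anti-inflammatory and oxidative phosphorylation sets did not pass. Mmp8, Socs3, Thbd and C5ar1 did not pass without 6 of the 8 libraries, each taken singly. Cox5a, Slc16a3 and Gapdh did not pass without 4, Cat and Pkm without 3, and Cd8a, Blnk and Sdhb without 2. S100a9, Serping1 and Cd79b did not pass without 7 of the 8 libraries, each taken singly.

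**Figure D3:**
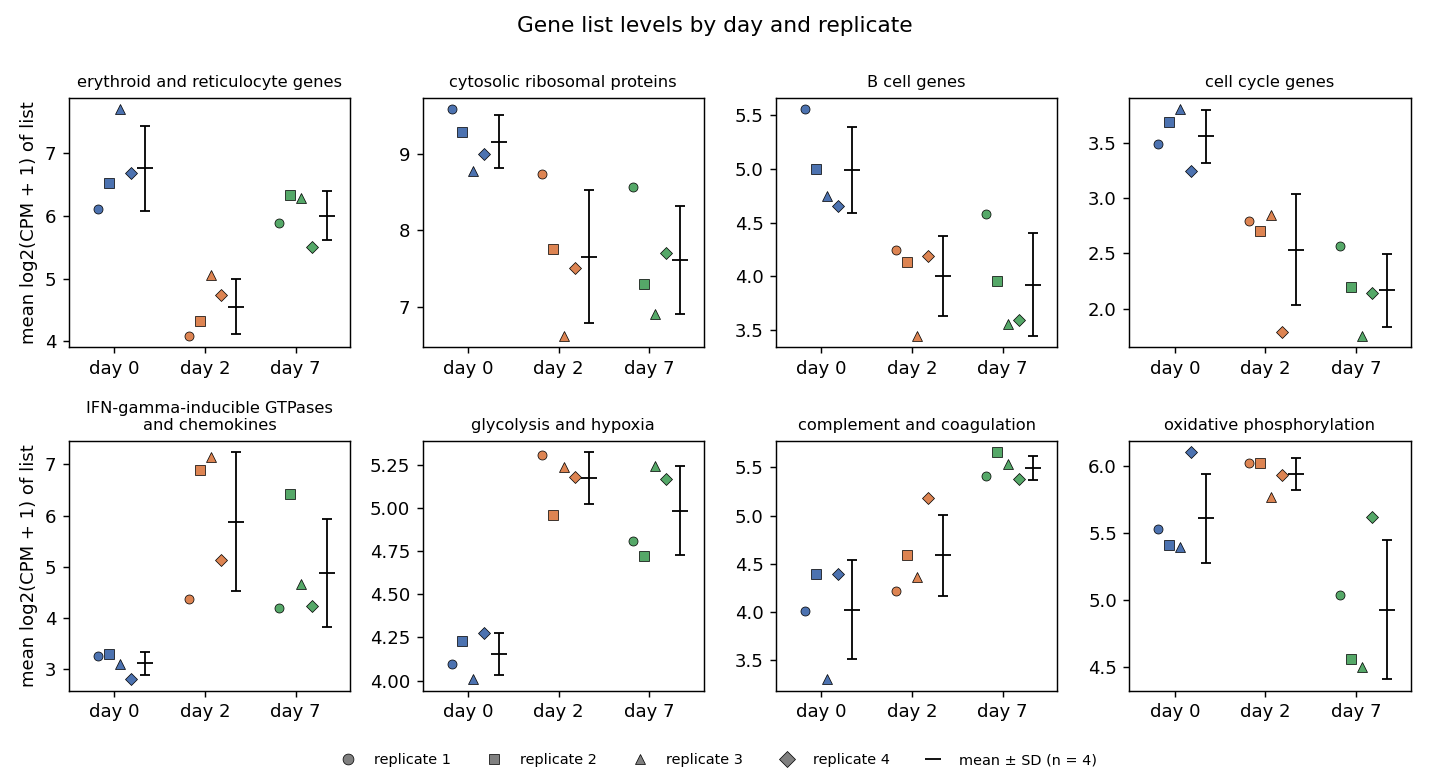
Mean log2(CPM + 1) of the tested genes of 8 lists in each library at day 0, day 2 and day 7, with a marker shape per replicate number and bars for the mean and SD of 4 libraries. The erythroid genes were at 6.76 on average at day 0 and 4.55 at day 2, and the complement genes at 4.02 at day 0 and 5.50 at day 7.

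The comparison of day 7 with day 2 asks what changed within the infection. Of the erythroid genes 8 of 31 were higher at day 7 than at day 2, and 12 of 37 oxidative phosphorylation genes were lower, while 0 lists passed as sets with an estimated correlation between genes. In all, 489 genes were higher and 1022 lower at day 7 out of 6889, and 1010 were higher and 1423 lower with the replicate block. The higher genes made up 32.4% of the calls, and this share varied with the setting. It was 42.3% after quantile normalization and 27.1% with library totals. With only the groups compared in the filter and fit it was 24.0%, and against a fold of 1.5 it was 18.9%.

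Of 31 erythroid and reticulocyte genes 8 were higher and 0 lower at day 7 than at day 2, also when adjusted over the list alone, and 18 were higher with the replicate block. Bpgm rose by 5.10 (SE 0.84, limma adjusted p 0.00123), to 9.13 ± 1.93 (SD, n = 4) against 11.17 ± 0.40 at day 0. Fech rose by 3.24 (SE 0.70, limma adjusted p 0.00565) and Blvrb by 3.27 (SE 0.44, limma adjusted p 0.000413). Within the limits given for day 2, the largest rises also included Ranbp10, Slc25a39, Kel, Alad, Cyp4b1 and Arl4a, at 3.24 to 4.06. Of these only Kel is in the erythroid list. Alas2, which is in the list, did not rise, at -0.42 (SE 0.68, limma adjusted p 0.723). Of 37 oxidative phosphorylation genes 12 were lower and 1 higher, also when adjusted over the list alone, and 15 and 2 with the replicate block. Sdhb fell by 4.57 (SE 0.64, limma adjusted p 0.000573), Ndufa1 by 2.70 and Ndufb5 by 2.31, Cox6c went from a mean log2(CPM + 1) of 9.41 to 5.41, and Cox8a rose by 1.36 (SE 0.41, limma adjusted p 0.0319). Within the limits given for day 2 the largest falls were in Hsph1, Psmc6, Klf10, Pxk, Smndc1, Rad21, Sdhb and Emb, from -5.40 to -4.38. The chaperone gene Hsph1 fell by 5.40 (SE 0.85, limma adjusted p 0.000988) and the proteasome gene Psmc6 by 5.18 (SE 0.55, limma adjusted p 0.000183). The cohesin gene Rad21 fell by 4.69 (SE 0.44, limma adjusted p 0.000150).

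The acute phase gene Hp rose by 3.44 between day 2 and day 7 (SE 1.06, limma adjusted p 0.0338). Gbp2 fell by 3.28 without passing, at a limma adjusted p of 0.150, and passed with the replicate block at 0.0311. Cd8a fell by 1.85 at a limma adjusted p of 0.0904, and passed with the block at 0.0393. Slc11a1, Tlr4, Cd14, S100a8 and S100a9 did not pass, at -0.17, 0.26, -0.24, 1.31 and 0.64. The changes of Irgm1, Ifng, Il1b, Tnf, Lcn2, Cd79a, Ncr1, Pf4 and C1qa did not pass either, and lay between -0.36 and 1.06. With camera in limma 2 of 33 lists passed, the erythroid genes at an adjusted p of 1.57e-05 and oxidative phosphorylation at 0.00156, and 0 lists passed with an estimated correlation, where the smallest adjusted p was 0.531 and 2 lists had an unadjusted p under 0.05. Complement and coagulation genes, with 2 of 17 higher, or 5 with the replicate block, passed with that block, at a camera adjusted p of 0.0168 in limma against 0.0670 without it. Hp did not pass without 5 of the 8 libraries, each taken singly, and Cox8a without 6.

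Day 2 and day 7 shared part of their differences from day 0. Of the genes called in both, 175 were higher and 55 lower on both days, and 24 went opposite ways, such as Psmc6 and Smndc1, which were above day 0 at day 2 and below it at day 7 and were chosen after their values were seen. With the replicate block the 3 counts were 319, 140 and 78. Independent lists of these sizes would share 22.6 higher and 19.7 lower genes, but the comparisons share their day 0 libraries and are not independent. Simulated unchanged groups that shared simulated day 0 libraries had 0 genes called in both in the same direction, over 100 simulations. Unchanged genes give next to no calls, so this 0 was fixed in advance and is no reference for the shared counts. Across the 6889 genes, which are not independent replicates, the log2 fold changes of the 2 days had a correlation of 0.568 against 0.50 simulated, and a covariance of 0.876 against 0.166 simulated. When the day 0 libraries were split between the comparisons the covariance was 0.759 on average over 6 splits, and 1 to 12 genes were called in both in the same direction.

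Each named gene that passed, except S100a9 at day 7, moved the same way in 4 of 4 same-numbered pairs of libraries. For the largest rises and falls this was fixed in advance, since they were chosen for values that do not overlap between the days. Cxcl9, Cxcl10, Nos2, Il6, Il10, Elane, Camp, Cd3e and Cd4 were too low to test. Ly6g was not analysed here. Genes of near-identical families, such as the guanylate-binding proteins, the hemoglobins and the ribosomal proteins with their pseudogene copies, can share reads and are uncertain to that extent.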

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

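The tests of liver RNA, of hepatic genes switched on and of the erythroid share were chosen only after the result was seen. What the splits below would show for the gene counts was corrected in writing after those counts were seen, and the splits for lists and for the overlap were added then.

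In each day's 4 libraries, a library was marked when its gap to the nearest of the other 3 took up most of the range of the 4. This was looked for in 3 groups of total counts, 42 groups of list means and 327 groups of named genes, and found in 1, 2 and 12 of them, while chance gives about 1 in 20 groups. The total count of the day 0 library numbered 3 was 8930009, against 16563564 to 17583449 in the others (gap of 0.882 of the range). The mean of the B cell genes was low in the day 2 library numbered 3 (0.856) and that of the cell cycle genes in the day 2 library numbered 4 (0.869). Single libraries were high for Hp and Serping1 in day 0 number 4 (0.830 and 0.892), Gbp7 in day 0 number 1 (0.857) and Ube2c in day 0 number 3 (0.856). They were also high for Arg2 and Kel in day 2 number 3 (0.903 and 0.952), Sod2 in day 7 number 2 (0.912), Rpl6 in day 7 number 1 (0.913) and Ldha in day 7 number 4 (0.836). Single libraries were low for Alas2 in day 2 number 2 (0.895) and for S100a9 and Ralgps2 in day 7 number 1 (0.870 and 0.833). Hp stood at a log2(CPM + 1) of 10.85 in day 0 number 4 against 6.63 to 7.35 in the others, and S100a9 at 0 in day 7 number 1 against 10.61 to 12.21. Day 0 number 4 also held the largest share of the hepatocyte transcripts described below, at 2.28% of its counts. A link of this share with Hp and Serping1 was not tested.

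The differences from day 0 were not equal at day 2 and day 7 for some results, as tested by the difference between the 2 days in limma. Camera gave an adjusted p of 1.57e-05 for the erythroid genes, which were nearer to day 0 at day 7, and 0.00156 for oxidative phosphorylation genes, which were lower at day 7, and neither passed with an estimated correlation, at 0.669 and 0.753. Bpgm, Kel, Blvrb and Fech, of the erythroid list, had limma adjusted p of 0.00123, 0.00230, 0.000413 and 0.00565. Ranbp10, Slc25a39 and Alad, which are not in that list, were higher at day 7 at limma adjusted p of 0.00145, 0.00355 and 0.00157. Cyp4b1, Arl4a, Hp and Cox8a were also higher at day 7, at limma adjusted p of 0.00386, 0.00470, 0.0338 and 0.0319. Hsph1, Psmc6, Klf10, Pxk, Smndc1, Rad21, Sdhb and Emb were lower at day 7, at limma adjusted p of 0.000988, 0.000183, 0.000150, 0.000677, 0.000107, 0.000150, 0.000573 and 0.00249. The respiratory chain genes Cox6c, Ndufb5 and Ndufa1 were lower at 0.000278, 0.00122 and 0.00160.

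Hepatocyte transcripts were high in the libraries numbered 4 on all 3 days. The 16 hepatocyte genes held 2.28%, 0.855% and 0.539% of the counts of the libraries numbered 4 at day 0, day 2 and day 7, against at most 0.00704% in any other library, and Alb reached 13508 CPM at day 0. The median log2 excess over numbers 1 and 2 was at least 6.09 on each day, and 13 of the 16 genes were in excess by more than 1. Liver RNA in these libraries is thus a candidate source. The medians of the other lists of tissues outside the blood did not exceed 0.0101. Few of their genes passed the filter, with 5 of 15 endothelial, 3 of 13 muscle and 3 of 17 eye and skin genes. Medians near 0 were thus likely in advance and do not show that other tissues were absent. At most 3 genes of any of these lists were in excess by more than 1 on a day. Hepatic genes switched on by infection are argued against by the excess of 7.16 at day 0. How liver RNA would have entered, and whether the number marks an animal, stays open.

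Libraries of a day differed more from one another after infection, with a median SD of 0.377 at day 0, 0.556 at day 2 and 0.751 at day 7 (log2). Unequal depth is argued against as the whole cause, since the ratio of day 7 to day 0 was 1.99 as fitted and 1.82 with every library thinned to 5218045 counts. The ratio was 2.25 without the libraries numbered 4 and 1.79 without the 100 most abundant genes, so neither accounts for all of it. These ratios were above 1.5 when 1 library of each day was also left out. With library totals in place of TMM factors the ratio was 1.65, and 1.33 at the lowest with 1 library of each day left out. Different courses of infection in the animals stay open and were not tested.

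At day 2, 16 of 31 erythroid and 6 of 41 ribosomal protein genes were lower, and neither set passed with an estimated correlation, at camera adjusted p of 0.367 and 0.403 in limma. A lower share of erythroid RNA alone would raise the markers of other cell types alike, but the median changes of 18 mature neutrophil and 14 B cell genes lay 1.26 apart, at 0.18 and -1.08 (two-sided permutation p 0.00466, 100000 resamples). The permutation treats the genes of a list as independent, so its p does not measure the spread between libraries. These marker medians did not move alike. Their gap cannot decide whether a lower erythroid share lowered the erythroid and ribosomal protein genes. Changes in several cell types stay open. The labels give no cell counts.

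Other splits of the libraries tested whether chance could give as many calls. For day 2 against day 0, day 7 against day 0 and day 7 against day 2, fits of the 2 groups alone gave 1579, 726 and 847 genes, and 1 of 35 splits, the real one, reached that number in each case, the highest other being 0. This is a share under 0.05, but by splits that ignore the pairing. Same-numbered libraries were correlated, so these splits alone do not exclude chance. The 8 splits that part all 4 pairs are too few for a share under 0.05, and with the replicate block the real one gave 3014, 1153 and 1590, the highest other being 0. For the 3 days together 1 of 100 drawn splits, the real one, reached 1817 genes, and the highest other was 700. This share under 0.05 also rests on splits that ignore the pairing, so it does not exclude chance either. Among drawn splits with each number once per group the highest other was 254 genes, and such splits are too few for a share under 0.05. For the genes called at both day 2 and day 7 in the same direction, 2 of 100 drawn splits reached 230, and the other of them gave 235. That share is under 0.05, but the drawn splits ignore the pairing, so chance is not excluded for the overlap. Among drawn splits with each number once per group the highest other overlap was 137, and such splits are too few for a share under 0.05. The drawn splits were not fitted with the block, where the real count was 459. For the number of gene lists that passed chance is not excluded, since 5 of 35 splits gave 9 or more at day 2 (highest other 12), 3 of 35 gave 9 or more at day 7 (highest other 10) and 25 of 35 gave 3 or more for day 7 against day 2 (highest other 11). These splits too ignore the pairing. The 8 splits that part all 4 pairs are too few for a share under 0.05, and the highest other among them was 7, 9 and 3 lists.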

How the results depend on the processing

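The alternatives with voom weights, library totals without TMM factors, unsummed transcripts and the libraries numbered 4 left out were chosen only after the data were seen. So were the settings for the overlap other than the block and the split of day 0. For the gene lists, no filter and a pseudocount of 0.1 were not planned either.

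The counts of genes for day 2 against day 0, day 7 against day 0, day 7 against day 2 and the 3 days together were 911, 740, 1511 and 1817. With the replicate block they were 1760, 1275, 2433 and 3030, and the overlap of day 2 and day 7 went from 230 to 459 genes. All genes called without the block were also called with it in the 3 comparisons of days. The block removes the differences between numbers from the residual spread, and the median SE fell from 0.444 to 0.359. The block ended the call of the MHC class I genes at day 2 and of the anti-inflammatory genes at day 7, added that of complement genes for day 7 against day 2, added S100a8, Tnf, Gbp2 and Cd8a as given in the comparisons, and changed no other call of a list or of a gene reported here. Without the libraries numbered 4 and with the block the counts were 1493, 1244, 2504 and 2927.

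Against a fold of 1.5, a stricter test, 354, 333 and 541 genes passed, and 125 in the overlap. With only the groups compared in the filter and fit, 1706 genes passed for day 2 against day 0 and 846 for day 7 against day 2, with 5979 and 5694 tested. Over the same 6889 genes such fits gave 1579 and 847. Leaving out 1 library at a time gave 499 to 827, 481 to 943, 918 to 2011 and 1297 to 2408 genes, and 146 to 305 in the overlap. For day 2 the count was 517, 499 and 508 without day 0 number 1, 2 and 3, and 577 and 508 without day 2 number 2 and 3. For day 7 against day 0 it was 481 and 491 without day 0 number 2 and 3, where the overlap was 147 and 146. For day 7 against day 2 it was 918 without day 2 number 2. With the day 0 libraries split between the comparisons the overlap was 6 genes on average (1 to 12), with fewer libraries in each. The other settings kept the counts within 1.5 times.

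With an estimated correlation 0 lists passed camera in each comparison, against 9, 11 and 2 with the preset one. Without 1 library the lists that passed were 6 to 12 for day 7 against day 0, and 6 without day 7 number 2. The B cell, erythroid, cell cycle and ribosomal protein lists at day 2, the B cell, cell cycle, ribosomal protein, complement and glycolysis lists at day 7, and both lists for day 7 against day 2 passed in the 10 other settings run for lists and without each library. The others were lost in at least 1 setting or without 1 library, with adjusted p of up to 0.130 over the settings. MHC class I genes did not pass without day 0 number 2 or 3 or day 2 number 2 or 4, and platelet genes without day 2 number 4. At day 7 the interferon-gamma and mature neutrophil genes did not pass without day 7 number 2, and oxidative phosphorylation without that library or day 0 number 4. The secondary granule and the anti-inflammatory genes each failed without 5 of 8 libraries. Without the libraries numbered 4, oxidative phosphorylation genes passed at day 2 as higher, at an adjusted p of 0.0204. The erythroid genes passed at day 7 as lower after quantile normalization (0.0349) and without a filter (0.0492). Skeletal and cardiac muscle genes, too few to test otherwise, passed for day 7 against day 2 without a filter (0.0169). The cause of these changes was not tested.

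Of the named genes that passed, 17 of 50 at day 2, 17 of 54 at day 7 and 2 of 22 between these days did not pass in some setting, most of them against a fold of 1.5. Without some single library 10, 15 and 2 did not pass, with the most lost, 9, 13 and 2, without day 0 number 1, day 0 number 2 and day 2 number 1. None of the named genes that passed changed direction under any of these settings. Scaling shifted the median of all genes by 0.11 and 0.15 (log2) at day 2 and day 7 with median-of-ratios factors and by -0.22 and -0.25 with library totals. The planned DESeq2 alternatives were not run, by the choice to go by the deposited log2 unit, although the recovered counts would have allowed them.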

Other observations

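The tests of the Y-linked genes and of the initiation factor genes were chosen only after the result was seen.

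Single transcripts held very different shares of the counts among the libraries of day 7. Mmp8 ranged from 0.00220% to 24.6%, Cd6 from 0.0721% to 23.5% and S100a8 from 0.0395% to 21.2%. Cd6 was thus abundant while Cd3e and Cd4 were too low to test. In the libraries numbered 4, Hbb-y, an embryonic globin gene, stood at 1008, 196 and 132 CPM at day 0, day 2 and day 7, and at no more than 10.1 CPM in the other libraries. The first 4 principal components held 29.1%, 22.9%, 21.4% and 7.21% of the variance.

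Lists that did not pass with camera in limma are given by median log2 fold change. At day 2 the medians were 1.32 for interferon-stimulated genes, -0.63 for pro-inflammatory cytokines and chemokines, 0.08 for anti-inflammatory genes, 0.08 for pattern recognition genes, -0.41 for inflammasome genes, -0.49 for acute phase genes and -0.19 for complement genes. They were 0.36 for MHC class II, 3.71 for secondary granule, -0.19 for primary granule, 0.18 for mature neutrophil, -0.17 for monocyte, -0.12 for plasma cell, -1.07 for T cell, -0.71 for T cell activation, -0.37 for cytotoxic and -0.07 for dendritic cell genes. They were 0.46 for oxidative phosphorylation, 0.20 for lysosome, 0.35 for unfolded protein response, -0.45 for apoptosis, -0.14 for immediate early, -0.97 for endothelial and -0.65 for hepatocyte genes. The adjusted p of these lists ranged from 0.116 to 0.926. T cell genes had a negative median with a mean of 0.14, since Cd6 rose by 8.09. The inflammasome, complement, primary granule, monocyte, dendritic cell, apoptosis and immediate early genes also had negative medians with positive means.

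At day 7 against day 0 the medians were 0.83 for interferon-stimulated, -0.34 for pro-inflammatory, -0.03 for pattern recognition, -0.09 for inflammasome, 0.01 for acute phase, 0.32 for MHC class I, -0.10 for MHC class II, 0.17 for primary granule and 0.35 for monocyte genes. They were -0.30 for plasma cell, -0.61 for T cell, -0.09 for T cell activation, -0.12 for cytotoxic, 0.03 for dendritic cell, -0.36 for erythroid and -0.49 for platelet genes. They were 0.19 for lysosome, -0.24 for unfolded protein response, -0.02 for apoptosis, 0.08 for immediate early, -0.32 for endothelial and -0.17 for hepatocyte genes. The adjusted p ranged from 0.0741 to 0.975. The median, the mean and the direction of the test differed in sign for pattern recognition, inflammasome, MHC class II, T cell, T cell activation, cytotoxic, apoptosis, immediate early and hepatocyte genes.

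Between day 2 and day 7 the 31 lists that did not pass had medians from -1.28 for MHC class I and -1.03 for interferon-gamma-inducible genes to 1.03 for complement genes, with adjusted p from 0.0670 to 0.989. Unfolded protein response genes had 6 members lower and 1 higher, with a median of -0.80. Monocyte genes had 4 higher and 0 lower, or 6 and 1 with the replicate block, with a median of 0.68. The signs differed for inflammasome, MHC class II, secondary granule, primary granule, mature neutrophil, B cell, T cell, ribosomal protein, lysosome, apoptosis and immediate early genes. They did not differ for any list that passed in the 3 comparisons.

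The Y-linked genes Ddx3y and Eif2s3y fell by 2.14 and 2.26 between day 0 and day 7. RNA from female cells at day 7 is argued against as the cause. Xist, looked for as a sign of female cells, had a highest count of 0 in any library. The X-linked copies also fell, the smaller of these changes being -1.91. Of the genes named Eif, which code for translation initiation factors, 11 of 46 were lower at day 7 and 0 higher, or 13 and 1 with the replicate block, with a median of -0.56. This set was picked after its values were seen, so its camera p of 0.0233 with an estimated correlation, and 0.0722 with the replicate block, decides nothing.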
